A study of Mus musculus with 2 samples.

How the data were processed

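The series holds 2 mouse single-cell RNA-seq libraries, 1 per age, made from polyadenylated RNA of living cells. The embryonic day 18 (E18) library came from CD1 mice and held the tissue dorsal to the lateral ventricles, cortex and dorsal ventricular-subventricular zone (V-SVZ) together. The postnatal day 2 (P2) library came from Emx1Cre;R26Eyfp fl/fl mice, in which cells descending from the Emx1-expressing cortical primordium carry EYFP, and held the dorsal and lateral V-SVZ after the cortex had been taken off. Both suspensions were digested with papain and sorted for cells negative for propidium iodide and positive for DRAQ5. Age, dissection, mouse line and library therefore cannot be separated in any comparison between the libraries. The barcode sets of the libraries shared 0 sequences and differed in kind: 6 E18 and 0 P2 barcodes began with AAACCT, and 0 and 4 with AAACCC. The chemistry of each library is not given in the sources used here, so a difference in it cannot be separated from age either.

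The deposited values are counts: per the file headers, the authors ran Cell Ranger 4.0.0, and per the labels they used version 4 against mm10, which gave raw UMI counts per gene and cell barcode without normalization. The deposited lists of genes and barcodes hold names only, a type of value recorded as other. Cell calling and aligner settings by the authors are not given in the sources used here. The E18 matrix had 2922 barcodes and 31053 genes with 19986915 UMIs, and the P2 matrix 2778 barcodes and 31054 features with 42572208 UMIs, the additional feature being EYFP. Median UMIs per barcode were 6292.5 at E18 and 11764 at P2.

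Cells were kept with 500 or more genes and with 10% or less of their UMIs from mitochondrial genes. This removed 291 E18 and 336 P2 barcodes. Doublets were scored with Scrublet in scanpy 1.11.5, at an expected rate of 0.05. The automatic threshold called 7 E18 cells (0.266%) and 4 P2 cells (0.164%), too few to serve as a working call, so the plan to remove the called cells alone was replaced. Instead, the highest 5% of scores set a limit in each library, and all cells at or above it were dropped from every class, sum and share. With tied scores these were 135 cells at E18 (5.13%) and 146 at P2 (5.98%). The automatically called cells among them were left out before clustering, and the others took part in it. The dropped cells had a median of 8045 UMIs at E18 and 33441.5 at P2. This left 2496 E18 cells with a median of 6574 UMIs and 2296 P2 cells with a median of 12525.

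Each library was clustered by itself: log-normalised counts, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). EYFP, mitochondrial, haemoglobin and sex-linked marker genes took no part in it. No annotation of cells by the authors was used here. The resulting 16 E18 and 19 P2 clusters were named from 20 fixed marker lists, and each class name stands for cells that are like that type by those markers. A name needed 4 detected markers and a mean level over its markers of at least 0.5 of the highest cluster. Among names within 0.1 of the best, the one with most markers among the 10 leading genes of the cluster was taken. Cells with 4 or more markers of a vascular or immune class inside a cluster of another kind were set aside: 1 endothelial and 5 mural cells at E18 and 2 microglia-marker cells at P2. By the same rule 2 P2 cells joined the ependymal class. The remaining unnamed P2 cluster held 29 cells.

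Counts were summed over the cells of a class and scaled by all UMIs of the class to CPM. Ratios are log2 of P2 over E18, or of EYFP-positive over EYFP-negative cells. With 1 library per group no test could be run, and no p-value is given. All intervals are 95% and cover counting error only: exact Poisson for sums, exact conditional for ratios, and exact Clopper-Pearson for shares. Where 1 group held 0 UMIs, its level was set to a floor of 3 UMIs over the group. Such ratios are given at the floor, and their intervals can reach smaller differences. The stem cell contrast was planned on EYFP-positive P2 cells if at least 100 were found. As 37 were found, all P2 cells of the class were used, the stated fallback, with the EYFP-positive cells as an alternative. Other classes were compared where each library held 50 or more cells and no cluster of the class was led by markers of another class.

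The 12 genes highest and the 12 lowest in each stem cell contrast were named, and 5 each in the other classes, some of which are not reported here. Genes with 50 or more CPM in 1 group were ranked by the bound of the interval nearest 0. Left out were mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed predicted genes, EYFP, and genes below 25% of their highest class in the same library, which free RNA can supply. For 21 fixed gene lists the median log2 ratio was taken over members with 10 or more UMIs. Its percentile came from 10000 random lists of the same size matched on expression, and its interval from 1000 Poisson draws. Aldoa was left out because 2 features bear that symbol. List members are named as examples where they had 20 or more CPM in 1 group and the largest ratios. Gene positions are from the GENCODE M21 annotation of GRCm38.

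The groups, the marker and gene lists, the rule for naming genes and the 22 alternative settings apart from 7 were fixed before the data were examined. Settled after the data had been seen were the handling of doublets, for which 5 schemes were run before 1 was kept, the numerical details of the naming rule, and the rule for setting cells aside. An earlier limit in that last rule split the ependymal cluster. The limit now used repaired that split, and with it a P2 cluster of 54 cells received the name maturing astrocyte where other schemes placed it in the stem cell class. This border is open, and for part of the lists values with both classes pooled are also given. Alternatives covered the cell filter, doublets, cluster resolution, joint clustering, TMM scaling (edgeR 4.0.16 in R 4.3.3), scaling without mitochondrial, ribosomal protein and haemoglobin UMIs, weighting each cell alike, EYFP thresholds, cycling cells and expression minimums.

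The interval and list methods were tested on simulated data built from the stem cell counts. Intervals held the true ratio for 96.0% of 3297 unchanged genes and for 97% and 98% of the genes changed 2-fold and 4-fold (100 each, raised or lowered). The simulated counts had Poisson error alone, so this checks the computation and not the spread between cells or libraries. Shares of cells with EYFP were computed on all UMIs and after thinning each cell to 3000 UMIs. The remaining computations used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.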

Results

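Gene expression was counted in single cells of 2 mouse brain libraries to follow the dorsal V-SVZ, the germinal zone lining the lateral ventricles, across birth. The E18 library held cortex and dorsal V-SVZ of CD1 mice, and the P2 library held dorsal and lateral V-SVZ of mice in which cortically derived cells carry EYFP. The E18 library had 19986915 UMIs in 2922 barcodes and the P2 library 42572208 UMIs in 2778 barcodes. Each age had 1 library, so every comparison below gives values with counting intervals, without a test, and age cannot be separated from dissection, mouse line or library. Values are deposited UMI counts summed over the cells of a class and scaled to CPM.

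The first comparison asked which cell classes each dissection held. Clusters named excitatory neurons made up 73.3% of the 2496 E18 cells (71.5 to 75.01) and 9.41% of the 2296 P2 cells (8.24 to 10.7), from which the cortex had been removed. Clusters named inhibitory neuroblasts or interneurons made up 12.02% at E18 (10.8 to 13.4) and 50.7% at P2 (48.6 to 52.7). These names include clusters with more markers of another class than of their own among 10 leading genes, so neither class was compared between the ages. They were E18 clusters 1, 2 and 8 (323, 283 and 136 cells; intermediate progenitor or striatal markers) and P2 cluster 7 (137 cells; a striatal marker). Cycling cells formed 4.25% at E18 (3.49 to 5.11) and 13.3% at P2 (11.9 to 14.7). Radial precursors or neural stem cells, here the stem cell class, formed 3.65% at E18 (2.95 to 4.46) and 1.87% at P2 (1.36 to 2.51).

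Some names were given in 1 library only. Excitatory intermediate progenitors formed 4.17% of E18 cells (3.42 to 5.03). At P2, inhibitory-lineage intermediate progenitors and striatal projection neurons each formed 6.88% (5.88 to 7.99; cluster 10, with 83 of the 158 progenitors, was led by replication genes such as Mcm3 and Uhrf1 and is not in the cycling share), maturing astrocytes 2.35% (1.77 to 3.06) and ependymal cells 1.92% (1.40 to 2.56). Oligodendrocyte precursors formed 2.00% at E18 (1.49 to 2.63) and 3.53% at P2 (2.81 to 4.37), and microglia 0.401% (0.192 to 0.736) and 1.87% (1.36 to 2.51). A P2 cluster of 29 cells led by Ebf1 and Isl1, 1.26% of cells (0.847 to 1.81), stayed unnamed. The shares reflect the dissections and the sort for living cells, and no direction with age was read from them. The P2 stem share was 5.84% with a mitochondrial limit of 5%, 5.05% at Leiden resolution 0.5 and 3.19% with doublets kept. In the first 2 of these settings no P2 cluster was named maturing astrocyte.

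**Figure D1:**
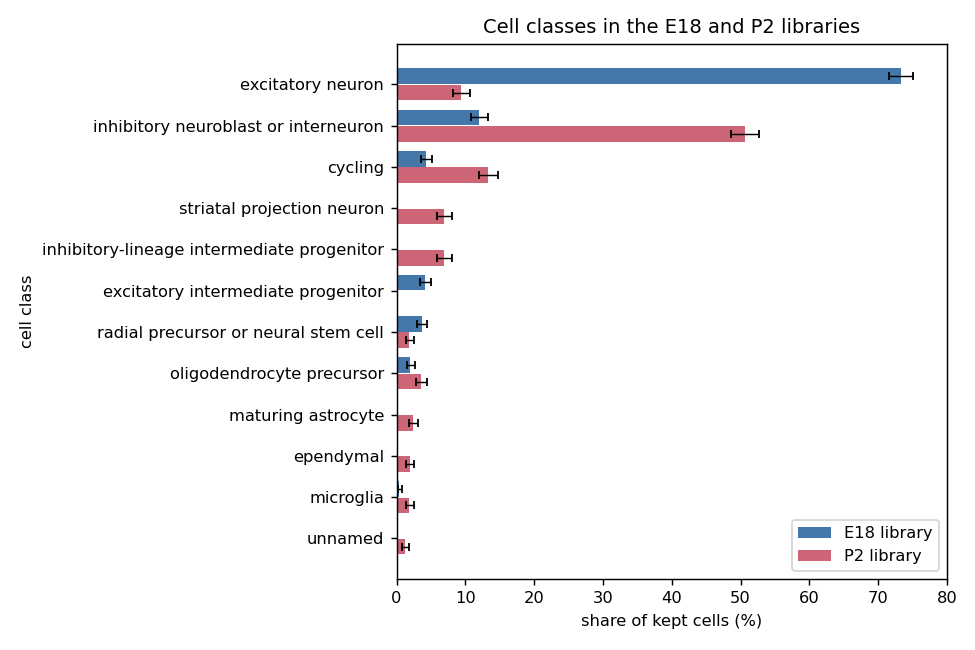
Share of kept cells (%) in each cell class of the E18 library (blue) and the P2 library (red), with exact 95% binomial intervals as error bars that cover counting error only. Excitatory neurons form 73.3% of E18 cells, and inhibitory neuroblasts or interneurons form 50.7% of P2 cells.

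The second comparison set the stem cell class of the P2 library against that of the E18 library. Astroglial genes and genes tied to quiescent adult stem cells were higher in the P2 class, and glycolysis genes were lower. Subpallial patterning genes, immediate early genes and interferon-related genes were also higher in the P2 class, whereas several genes of the excitatory neuronal lineage were lower. The contrast used 43 P2 cells with 794537 UMIs (cluster 13) and 91 E18 cells with 549713 UMIs (cluster 10), median 19526 and 6179 UMIs per cell. Genes that led these clusters, among them Pla2g7, Sparcl1 and Hopx at P2 and Mt2, Apoe and Sparc at E18, helped to define the class itself. The median log2 ratio of all genes was 0.21, and TMM scaling moved every ratio by -0.13.

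Of 23 astroglial genes, 17 were higher and 6 lower in the P2 class, with a median log2 ratio of 0.89 (0.74 to 0.95), at percentile 100 of random lists. The matrix glycoprotein gene Sparcl1 stood at 2.48 (2.24 to 2.72), the glutamate transporter gene Slc1a2 at 2.48 (2.14 to 2.83) and the water channel gene Aqp4 at 2.13 (1.46 to 2.87). The neurotrophin receptor gene Ntrk2 stood at 1.93 (1.68 to 2.18). The metallothionein gene Mt2 went the other way, at -2.14 (-2.36 to -1.92), and Aldh1l1 stood at -0.45 (-0.77 to -0.13). Markers of maturing astrocytes had a median of 1.91 (1.56 to 2.29) in the same contrast. Of 19 measured genes of the adult quiescent stem cell list, 14 were higher, with a median of 0.57 (0.43 to 0.75) at percentile 99.8. Klf9, which encodes a Krüppel-like transcription factor, stood at 2.28 (1.56 to 3.08), Cpe at 2.22 (2.05 to 2.40) and the adhesion gene Vcam1 at 0.90 (0.54 to 1.28), while Hopx stood at -1.51 (-1.78 to -1.24). Of the 20 genes on that list, 10 also stand in another list.

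BMP and Id genes had a median of 0.86 (0.37 to 1.16) at percentile 98.6, with 8 of 11 higher. The BMP receptor gene Bmpr1b stood at 2.64 (0.94 to 5.00) and the BMP target Id1 at 1.08 (0.56 to 1.62), with Id4 at -0.49 (-0.68 to -0.29). Extracellular matrix and adhesion genes had a median of 0.72 (0.51 to 0.96) at percentile 99.7, with 11 of 14 higher. The proteoglycan genes Vcan and Cspg5 stood at 2.31 (1.49 to 3.23) and 1.57 (1.39 to 1.75), and Ncan at -0.51 (-0.71 to -0.31). Oligodendrocyte lineage onset genes had a median of 1.47 (0.83 to 1.79) at percentile 99.8, with Egfr at 1.69 (0.39 to 3.25) and Sox8 at 1.42 (0.58 to 2.35). Markers of oligodendrocyte precursors had a median of 1.47 (1.06 to 1.91).

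Glycolysis genes had a median of -1.02 (-1.19 to -0.72), below all 10000 random lists, with 7 of 11 lower and 4 higher. Ldha, which encodes lactate dehydrogenase A, stood at 804 CPM at E18 and 137 CPM at P2, a log2 ratio of -2.55 (-2.87 to -2.25). The enolase gene Eno1 stood at -1.56 (-1.78 to -1.34) and the triosephosphate isomerase gene Tpi1 at -1.38 (-1.67 to -1.11). The hexokinase gene Hk1 was higher, at 1.95 (0.56 to 3.68), and Gapdh stood at 0.02 (-0.13 to 0.17). The glycolysis list had a median of -0.52 when maturing astrocytes were pooled with the P2 class and -0.46 with the stricter mitochondrial limit. Oxidative phosphorylation genes had a median of -0.35 (-0.42 to -0.23) at percentile 10.1, with 15 of 17 lower, and of -0.10 at percentile 67.5 with maturing astrocytes pooled in. Hypoxia-responsive genes had a median of -0.39 (-0.82 to 0.27) at percentile 8.17.

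Proneural and newborn neuron genes split, with 7 of 13 lower, 6 higher and a median of -0.73 (-1.19 to 0.21). The proneural factor gene Neurog2 had 35 UMIs at E18 and 0 at P2, 16.9-fold lower at the floor. The intermediate progenitor factor gene Eomes stood at -2.85 (-6.08 to -0.62). In contrast, the migrating-neuron genes Dcx and Tubb3 stood at 2.97 (1.30 to 5.32) and 0.93 (0.39 to 1.49). Markers of excitatory intermediate progenitors had a median of -2.85 (-3.38 to -1.21), and those of inhibitory neuroblasts a median of 1.58 (1.05 to 1.97). The proneural median changed sign with doublets kept (0.61), without the cell filter (0.48) and over members with 50 or more UMIs (0.39).

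Subpallial patterning genes had a median of 2.05 (1.21 to 2.56) at percentile 99.9, with 6 of 7 measured members higher. The hedgehog effector gene Gli1 stood at 2.38 (0.87 to 4.34) with 4 and 30 UMIs, and the oligodendrocyte and ventral lineage gene Olig2 at 1.57 (0.56 to 2.73). Dlx1, a homeobox gene of inhibitory lineages, had 1 and 16 UMIs, a log2 ratio of 3.47 (0.78 to 8.86). Pallial patterning genes had a median of -0.45 (-0.95 to -0.12) at percentile 2.86, with 6 of 9 lower. The cortical homeobox gene Emx1 stood at -1.53 (-2.41 to -0.70) and Tfap2c at -0.95 (-1.52 to -0.38). With EYFP-positive P2 cells alone the subpallial median was 1.67 over 5 members and 1.51 (0.64 to 1.96) over all 7, and the pallial median -0.34. Pooled with maturing astrocytes the subpallial median was 3.19 and the pallial median -1.29.

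Dissociation stress genes, immediate early and heat shock genes that tissue handling can induce, had a median of 1.39 (1.00 to 1.88) at percentile 100, with 15 of 17 higher. Fosb stood at 3.66 (2.58 to 5.00), Junb at 3.57 (2.29 to 5.23) and Egr1 at 2.28 (1.72 to 2.88), with Hspa8 at 0.16 (0.03 to 0.29). All 8 measured interferon and MHC class I genes were higher, with a median of 1.02 (0.67 to 1.57) at percentile 98.0. The transcription factor gene Irf1 stood at 2.47 (1.13 to 4.17) and H2-D1 at 1.33 (0.58 to 2.14).

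S phase genes had a median of 0.28 (-0.20 to 0.57) at percentile 48.3 and G2 and M phase genes one of -0.01 (-0.55 to 0.41) at percentile 23.5. Pooled with maturing astrocytes, which then formed 97 P2 cells, the same lists had medians of 1.69 and 1.77. Notch pathway genes had a median of 0.12 (-0.45 to 0.34), within which the ligand gene Jag1 stood at 3.89 (1.95 to 6.99) and the effector gene Hes5 at -1.04 (-1.30 to -0.78). Embryonic progenitor genes had a median of -0.23 (-0.53 to 0.09) at percentile 13.9, and of -0.50 pooled, with the RNA-binding protein gene Igf2bp3 at -1.92 (-3.31 to -0.69), Tead2 at -1.55 (-2.12 to -0.999) and the intermediate filament gene Nes at 0.81 (0.44 to 1.19). Cholesterol synthesis genes stood at 0.12 (-0.09 to 0.29) and fatty acid oxidation genes at 0.05 (-0.16 to 0.24). Polycomb and DNA methylation genes stood at 0.58 (0.25 to 0.93) at percentile 89.9, with the Polycomb subunit gene Suz12 at 2.99 (1.54 to 4.93). The 5 measured ependymal and ciliary genes had a median of 0.88 (0.05 to 1.60) at percentile 80.7.

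**Figure D2:**
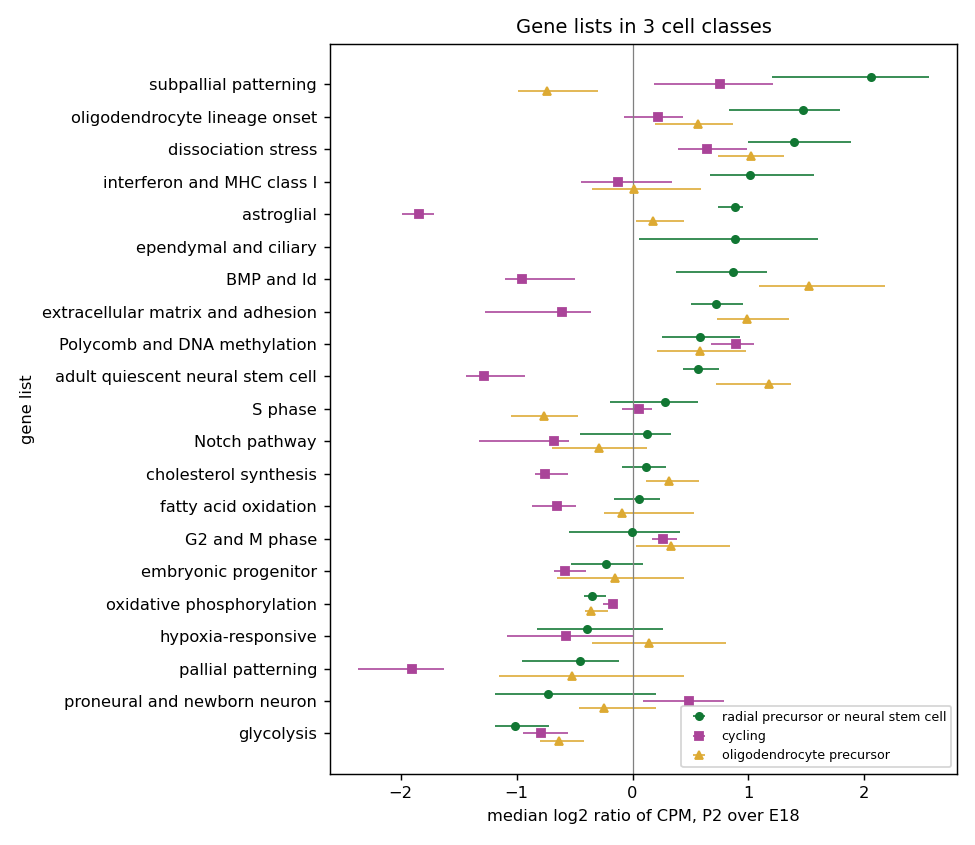
Median log2 ratio of CPM, P2 over E18, of each fixed gene list in the stem cell class (green circles), cycling cells (purple squares) and oligodendrocyte precursors (yellow triangles), with 95% intervals from Poisson draws. Glycolysis lies below 0 in all 3 classes, at -1.02, -0.79 and -0.63, while the astroglial list lies at 0.89 in the stem cell class and -1.84 in cycling cells.

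Among single genes of the stem cell class, Ramp1 had the highest bound (ENSMUSG00000034353, chromosome 1, 91179822 to 91225196 on GRCm38). This gene, which encodes an accessory protein of the calcitonin receptor-like receptor, had 1 UMI at E18 and 109 at P2, 1.82 and 137 CPM, a log2 ratio of 6.24 (3.73 to 11.55). Txnip, which encodes an inhibitor of thioredoxin, stood at 5.60 (3.07 to 10.92), Fam107a at 5.56 (3.03 to 10.88) and the kinase gene Plk2 at 5.28 (2.74 to 10.61). The noncoding gene AY036118 stood at 4.39 (2.80 to 6.70), the interleukin 11 receptor gene Il11ra1 at 4.17 (2.57 to 6.48) and the receptor gene Gpr37 at 4.93 (2.37 to 10.26). The stress-induced genes Klf4 and Ppp1r15a stood at 3.65 (2.57 to 4.99) and 3.79 (2.52 to 5.44). Cldn10, which encodes a tight junction claudin, stood at 3.08 (2.45 to 3.77) and Pla2g7, which encodes a secreted phospholipase, at 2.96 (2.48 to 3.48). Some of these genes were also found in P2 microglia. Ramp1 stood there at 49.2 CPM, Txnip at 85.1 (88.1 in the P2 stem cell class) and Il11ra1 at 58.2 (98.2). Fam107a, Cldn10 and Gpr37 stood at 0 CPM in microglia. The source of the UMIs in microglia was not tested.

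Dct led the genes with lower levels at P2 (ENSMUSG00000022129, chromosome 14, 118012790 to 118052244). It encodes dopachrome tautomerase and had 61 UMIs at E18 and 0 at P2, 29.4-fold lower at the floor and at least 23.2-fold by the counting interval. Creg2 had 47 and 0 UMIs, 22.6-fold lower at the floor and at least 17.7-fold by the interval. The adenosine receptor gene Adora2b had 30 and 0, 14.5-fold lower at the floor and at least 11.0-fold by the interval. Tmem108 stood at -5.39 (-8.47 to -3.47), Mfap4 at -4.55 (-6.03 to -3.37), Hddc3 at -4.26 (-6.19 to -2.82) and the small heat shock gene Cryab at -3.75 (-6.12 to -2.06). Insm1, which encodes a zinc finger factor of basal progenitors, stood at -2.98 (-3.71 to -2.31), the insulin-like growth factor binding protein gene Igfbp2 at -2.59 (-2.89 to -2.30) and the glyoxalase gene Glo1 at -2.24 (-2.45 to -2.04).

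Of these 24 genes, 13 stood on the same side of 0, beyond counting error, in both other classes compared, cycling cells and oligodendrocyte precursors. They were Txnip, AY036118, Plk2, Fosb, Klf4 and Ppp1r15a among the higher, and Mfap4, Hddc3, Insm1, Igfbp2, Ldha, Glo1 and Mt2 among the lower genes. This count takes in small ratios, such as Insm1 in cycling cells at -0.24 (-0.38 to -0.10), and the share among all ranked genes is not given here. Pla2g7 had the opposite sign in cycling cells, at -3.49, and Tmem108 in oligodendrocyte precursors, at 0.99. With EYFP-positive P2 cells alone 23 of the 24 were named again, and with maturing astrocytes pooled into the P2 class 10 were.

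**Figure D3:**
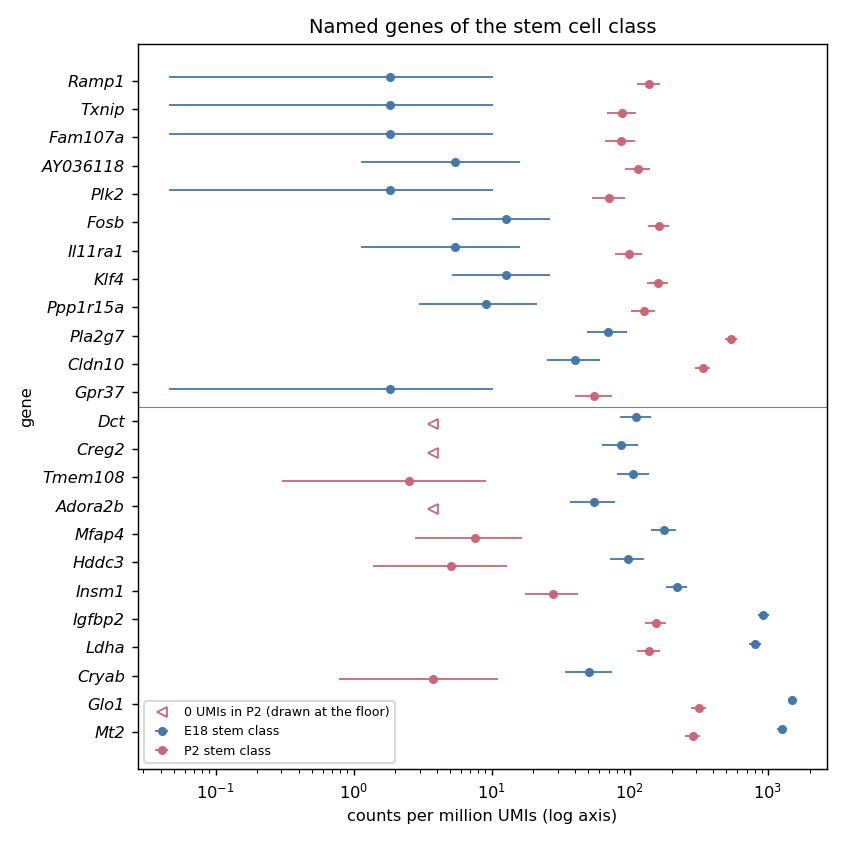
CPM on a log axis of the 24 named genes in the E18 stem cell class (blue) and the P2 stem cell class (red), with exact 95% Poisson intervals; an open triangle marks 0 UMIs at P2, drawn at the floor of 3 UMIs. Ramp1 had 1.82 CPM at E18 and 137 at P2, and Ldha 804 and 137.

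The third comparison stayed within the P2 stem cell class and set 37 cells with EYFP, of cortical origin, against 6 cells without. Pallial patterning genes were higher in the cells with EYFP and subpallial patterning genes were lower. The pallial list had a median log2 ratio of 0.86 (0.31 to 1.30) at percentile 99.97, with 6 of 7 higher, and the subpallial list one of -1.41 (-2.47 to -0.30), below all random lists, with 5 of 7 lower. Markers of inhibitory neuroblasts had a median of -0.89 (-1.49 to 0.16) at percentile 0.90, with 5 of 6 lower. The LIM homeobox gene Lhx2 stood at 0.86 (0.16 to 1.67) and the doublesex-related gene Dmrta2 at 1.53 (-0.08 to 3.84). The ventral forebrain homeobox genes Six3 and Gsx2 stood at -6.46 (-11.88 to -3.67) and -4.41 (-6.96 to -2.35). These 2 ratios rest on 12 and 11 UMIs in the whole P2 stem cell class.

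Interferon and MHC class I genes had a median of 1.00 (0.13 to 1.15), the adult quiescent stem cell list 0.30 (-0.07 to 0.60), the BMP and Id list 0.45 (0.08 to 0.99) and the astroglial list 0.04 (-0.04 to 0.26). Dissociation stress genes stood at 0.54 (0.21 to 1.01), with Fos at 1.10 (0.58 to 1.67). Cntnap2, a neurexin family adhesion gene, had 153 UMIs in the cells with EYFP and 0 in the others, 6.39-fold higher with the others at the floor. Hopx stood at 2.84 (1.27 to 5.14), the hedgehog coreceptor gene Gas1 at 2.13 (1.27 to 3.14), the NF-kB inhibitor gene Nfkbia at 3.04 (1.15 to 6.10), the intermediate filament gene Gfap at 3.41 (0.90 to 8.73) and the cystatin gene Cst3 at 1.18 (1.05 to 1.31). Spire1 stood at 2.27 (0.88 to 4.16) and Rab6b at 3.38 (0.86 to 8.70), and Snx2, Nme7, Oxr1 and Plk2 had 60, 59, 59 and 56 UMIs in the cells with EYFP and 0 in the others. The imprinted noncoding gene H19 stood at -4.80 (-8.11 to -2.41), Sp5 at -5.32 (-10.88 to -2.16), As3mt at -4.58 (-7.92 to -2.10), S100a4 at -3.997 (-6.18 to -2.10) and Sqor at -4.32 (-7.71 to -1.71). The ephrin receptor gene Epha3 and the phosphatase subunit gene Ppp1r3g both stood at -3.36 (-5.02 to -1.77), the prostaglandin synthase gene Ptgds at -3.00 (-4.34 to -1.65) and Ngef at -3.00 (-4.42 to -1.58).

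The 6 cells held 88449 UMIs, so ratios with wide intervals in this contrast rest on few UMIs. Cells without an EYFP UMI can include labelled cells in which it was missed. Pooled with maturing astrocytes, as 57 cells with and 40 without EYFP, the pallial median was 1.65 and the subpallial median -1.65, while the stress median turned to -0.36. Of the pooled cells, 37 of the 57 with EYFP were stem cells and 34 of the 40 without were maturing astrocytes, so these values also set stem cells against astrocytes. The pooled groups differed in cycling genes too. S phase genes had a median of -1.22 (-1.45 to -1.03) and G2 and M phase genes one of -1.25 (-1.54 to -1.11), with 20 of 20 lower in each list. Cst3 turned to -0.15 with doublets kept, and with automatic doublet calls only the subpallial median turned to 0.084, the interferon median to -0.0040 and the BMP and Id median to -0.0041.

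**Figure D4:**
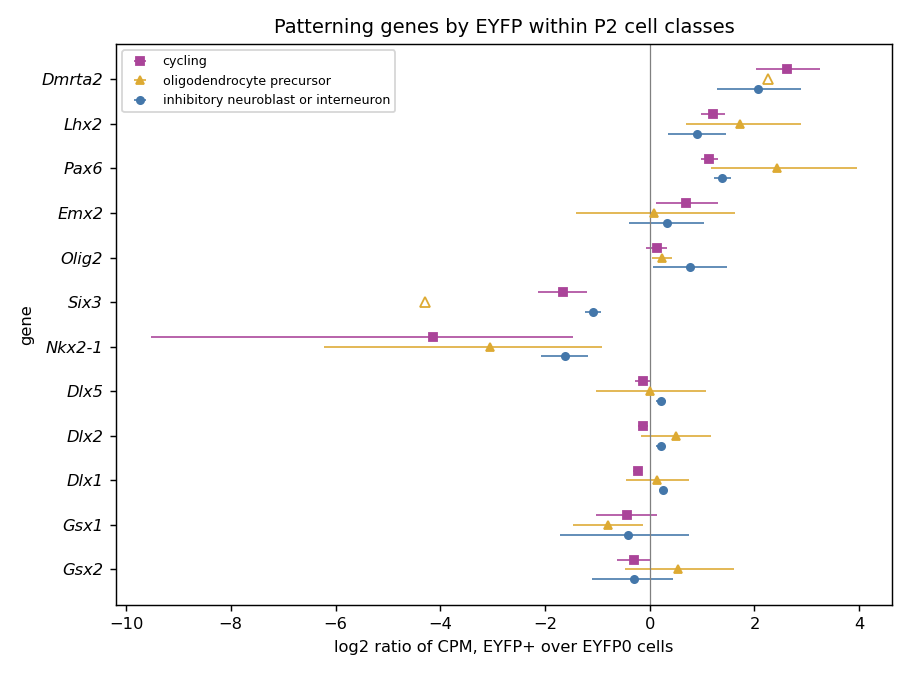
Log2 ratio of CPM, cells with EYFP over cells without, of patterning genes in 3 further P2 classes, with exact 95% intervals; open symbols mark 1 group at 0 UMIs. Pax6 stood at 1.14 in cycling cells, 2.43 in oligodendrocyte precursors and 1.39 in inhibitory neuroblasts or interneurons; these contrasts were chosen after the data had been seen.

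The fourth comparison asked which P2 classes held cells of cortical origin, read from EYFP. EYFP was found in 86.0% of stem cells (37 of 43, 72.1 to 94.7) and 81.9% of excitatory neurons (177 of 216, 76.2 to 86.8). It was found in 56.8% of oligodendrocyte precursors (45.3 to 67.8), 48.1% of inhibitory-lineage intermediate progenitors (40.1 to 56.2), 44.9% of cycling cells (39.2 to 50.7) and 37.0% of maturing astrocytes (24.3 to 51.3). Of 1163 inhibitory neuroblasts or interneurons 26.9% carried it (24.4 to 29.6), of ependymal cells 18.2% (8.19 to 32.7) and of striatal projection neurons 12.7% (7.91 to 18.9). Microglia, which do not descend from the cortical primordium, gave the background: 0 of 43, with an upper bound of 8.22%, at a median of 19431 UMIs. Median UMIs were 19526 in stem cells, 12250.5 in excitatory neurons, 15521 in oligodendrocyte precursors, 22472.5 in inhibitory-lineage intermediate progenitors, 27063 in cycling cells, 18624 in maturing astrocytes, 9812 in inhibitory neuroblasts, 21125 in ependymal cells and 13121.5 in striatal projection neurons.

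The EYFP level was 494 CPM in stem cells, 414 in oligodendrocyte precursors, 406 in inhibitory-lineage intermediate progenitors, 315 in excitatory neurons, 280 in cycling cells, 160 in maturing astrocytes, 120 in inhibitory neuroblasts and 26.0 in striatal projection neurons. Thinned to 3000 UMIs, EYFP was seen in 77.5% of stem cells (3 too shallow to use), 58.2% of excitatory neurons (15 too shallow), 39.5% of oligodendrocyte precursors (0), 45.1% of inhibitory-lineage intermediate progenitors (14), 37.5% of cycling cells (9) and 28.0% of maturing astrocytes (4). The thinned share was 16.9% in inhibitory neuroblasts (49 too shallow), 7.89% in ependymal cells (6), 3.25% in striatal projection neurons (4) and 0 of 36 in microglia (7).

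Clusters of inhibitory neuroblasts differed in EYFP. The share was 47.3% in cluster 3 (40.9 to 53.8), led by St18 and Sp8, and 36.8% in cluster 0 (31.2 to 42.7), led by Prokr2. It was 21.3% in cluster 5 (15.4 to 28.3), led by Nr2f2, 13.1% in cluster 7 (7.98 to 20.0), led by Six3 and with a striatal marker but none of its own class among 10 leading genes, and 11.9% in cluster 2 (8.11 to 16.6), led by Foxp2. Cluster 9, led by the medial ganglionic eminence gene Lhx6, had 11.9% (5.86 to 20.8). These clusters had median depths of 14451, 8573, 9825, 11095, 7913 and 10660.5 UMIs, and EYFP stood at 287, 137, 54.9, 18.3, 30.4 and 16.1 CPM. The stem cell share was 50% at Leiden resolution 0.5 and 54.9% with the stricter mitochondrial limit, settings in which no cluster was named maturing astrocyte.

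**Figure D5:**
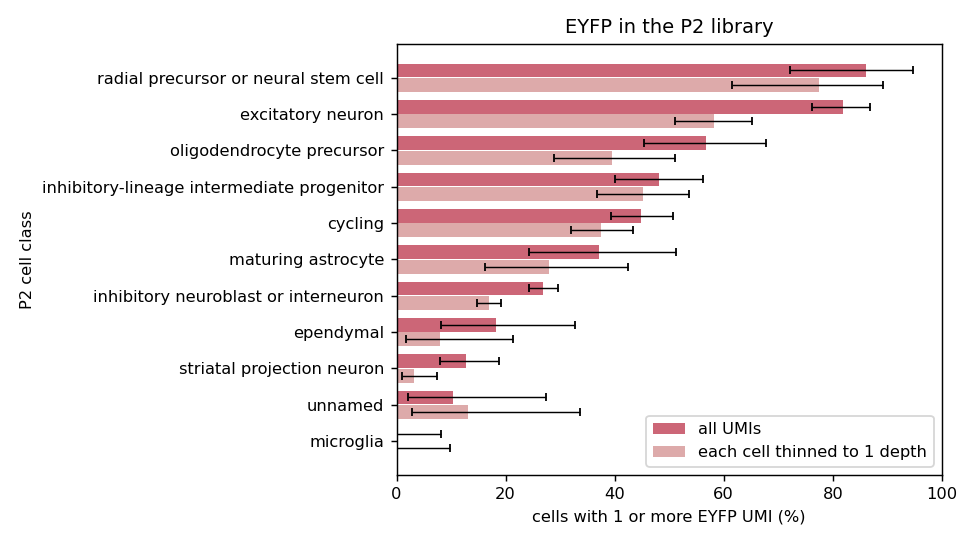
Share of cells (%) with 1 or more EYFP UMI in each P2 class, on all UMIs (dark) and with each cell thinned to 3000 UMIs (light), with exact 95% binomial intervals. Stem cells stand at 86.0% and 77.5%, and microglia at 0% in both.

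The fifth comparison asked which differences stood in other classes of the same libraries. In cycling cells, 305 at P2 (clusters 1 and 12) and 106 at E18 (cluster 9), astroglial and pallial genes were lower in the P2 library and subpallial genes higher. The astroglial median was -1.84 (-1.99 to -1.71) with 20 of 23 lower, and the pallial median -1.91 (-2.37 to -1.63) with 8 of 9 lower. Neurog2 stood at -5.72 (-6.58 to -4.95) and Emx1 at -4.93 (-5.89 to -4.05). The subpallial median was 0.76 (0.19 to 1.21), with 214 Six3 UMIs at P2 and 0 at E18. All 15 cholesterol synthesis genes were lower, with a median of -0.76 (-0.84 to -0.56). Polycomb and DNA methylation genes had a median of 0.90 (0.68 to 1.05), with Bmi1 at 1.74 (1.19 to 2.35), and dissociation stress genes one of 0.64 (0.39 to 0.98). Among genes that met the level and free RNA limits of the naming rule, S100a10, Rpgrip1, AY036118, the axon guidance gene Shtn1 and the imprinted gene Peg3 came first by the bound nearest 0, at 5.27, 5.22, 4.01, 3.74 and 3.64. By the bound nearest 0, Hopx, the matrix gene Tnc, Ccdc80, the glutathione transferase gene Gsta4 and the Notch effector Hes5 came first among lower genes, at -6.33, -4.88, -4.79, -4.62 and -4.40. The subpallial median was -0.09 with the stricter mitochondrial limit.

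In oligodendrocyte precursors, 81 at P2 (cluster 8) and 50 at E18 (cluster 14), S phase genes were lower in the P2 library. Among the 10 leading genes of cluster 8 were 4 markers of differentiating oligodendrocytes beside 5 of its own class, and cluster 14 had none of them. Mbp, which encodes a major myelin protein and also led the P2 cluster, stood at 7.19 (5.34 to 10.24). Enpp6, a gene of newly formed oligodendrocytes, had 0 and 209 UMIs, 16.4-fold higher with E18 at the floor. Ugt8a, which encodes a galactolipid enzyme, stood at 5.77 (3.28 to 11.08) and S100a6 at 5.73 (3.87 to 8.78). The S phase median was -0.77 (-1.05 to -0.47) with 18 of 19 lower, and Mcm2 stood at -1.96 (-2.69 to -1.22). Mfap4, Ppic, Tead2, Hddc3 and the bHLH gene Helt came first among lower genes by that bound, at -4.25, -4.96, -4.12, -3.54 and -3.41. The adult quiescent stem cell list had a median of 1.17 (0.72 to 1.37), the BMP and Id list 1.52 (1.09 to 2.18), with Bambi at 4.47 (1.95 to 9.79), and the stress list 1.02 (0.74 to 1.31).

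Glycolysis genes were lower in the P2 library in both classes, with medians of -0.79 (-0.95 to -0.56) in cycling cells and -0.63 (-0.80 to -0.42) in oligodendrocyte precursors. Ldha stood at -2.15 (-2.26 to -2.03) and -1.49 (-1.70 to -1.28) in them. The median of all genes was 0.41 in oligodendrocyte precursors, where TMM scaling moved every ratio by -0.29 and scaling without mitochondrial, ribosomal protein and haemoglobin UMIs by -0.20. The astroglial median of that class, 0.17, became -0.12 and -0.03 under those scalings.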

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

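Of the tests below, only those of the scaling and of doublets with labelled cells were written down before the result was seen, and all others were chosen afterwards.

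A difference between groups of cells marked 5 gene lists, whose median log2 ratio of P2 over E18 in the stem cell class differed from that in another class of the same libraries. For the astroglial list the stem cell median minus that of cycling cells was 2.73 (0.89 and -1.84). For the adult quiescent stem cell list it was 1.85 (0.57 and -1.28), for the BMP and Id list 1.82 (0.86 and -0.96) and for the matrix and adhesion list 1.33 (0.72 and -0.61). For the subpallial list the stem cell median minus that of oligodendrocyte precursors was 2.79 (2.05 and -0.74). These differences were not tested.

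Subpallial patterning genes were higher in the P2 stem cell class. Cells of lateral origin in the P2 class cannot be told apart as its cause: with EYFP-positive cells alone the median over all 7 members was 1.51 (0.64 to 1.96), at percentile 98.3 of random lists, and its lower bound lay at percentile 71.3. Free RNA is excluded by its prediction, since the lowest level in another P2 class was 5.25% of the stem cell level in the median member. Doublets could not be excluded: the 5 stem cells with most inhibitory neuroblast marker UMIs held 33.5% of the list's UMIs (26.7 to 40.9) and 17.5% of all UMIs.

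Glycolysis genes were lower in the P2 stem cell class. A difference between the libraries alike in every class fits, since the median was -0.63 in oligodendrocyte precursors and -0.79 in cycling cells. The scaling is excluded as the cause, since the median was -1.15 under TMM factors. Whether age, dissection, mouse line or another difference between the libraries lies behind it was not tested.

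EYFP was seen in 12.7% of P2 striatal projection neurons (7.91 to 18.9), a class that arises mainly outside the cortical primordium. Free RNA is excluded, since the upper bound in microglia was 4.13 CPM and the level in these neurons 26.0 (19.6 to 33.9). A uniform low level is excluded, since a Poisson spread would give 28.6% of cells with 1 or more UMI. Doublets with labelled cells would be excluded by the rule written beforehand, at a ratio of median UMIs of 1.15, but the resampling interval added afterwards (0.946 to 1.40) left this undecided, and a lineage origin remains open.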

How the results depend on the processing

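Of 22 alternative settings 7 were chosen after seeing the data. A value counted as the same inside the 95% counting interval of the reported one and as moved outside it. It counted as reversed where it changed sign and that interval excluded 0, so a sign change of a result whose interval includes 0, such as the proneural median, counts as the same or moved. Over 177 results the settings gave 2770 values, of which 2266 stayed the same, 483 moved and 21 reversed. Among 1124 values of named genes 1 reversed, Cst3 within P2, so every named stem cell gene kept its direction. Which genes were named depended more on the setting. Of the 24 stem cell genes, 10 were named again with the stricter mitochondrial limit, 10 with joint clustering and 11 at Leiden resolution 0.5. At resolution 2, 23 were named again, and 7 with a minimum of 200 CPM. Of 204 shares of cells 65 moved, and of 133 EYFP values 17. Except where stated, the cause was not tested. No paired analysis was possible because each age had 1 library and the libraries came from mice of different ages and lines.

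In the stem cell class the astroglial median ranged from 0.57 to 1.06, glycolysis from -1.24 to -0.46 and the subpallial list from 1.67 to 3.19, and the pallial median within P2 from 0.80 to 1.75. The proneural median (-1.03 to 0.61) and the G2 and M phase median (-1.39 to 2.35) changed sign. The P2 stem cell class held 42 to 117 cells.

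Without the cell filter, excitatory neurons formed 62.2% at E18, inhibitory neuroblasts 48.5% at P2 and stem cells 2.69% at P2, with EYFP in 57.7% of stem cells. The proneural median was 0.48 and the pallial median within P2 1.34.

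With 1000 or more genes and 5% or less mitochondrial UMIs, excitatory neurons formed 65.8% at E18 and 7.91% at P2, inhibitory neuroblasts 43.7% and stem cells 5.84% at P2, with EYFP in 54.9% of stem cells. Stem cell medians were 1.06 (astroglial), 1.24 (G2 and M phase), -0.46 (glycolysis) and 3.02 (subpallial), and the pallial median within P2 was 1.72. The stress median within P2 (-0.33) and the subpallial median of cycling cells (-0.087) reversed.

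With doublets kept, inhibitory neuroblasts formed 39.9% and stem cells 3.19% at P2, with EYFP in 70.5% of stem cells. The proneural median was 0.61 and that of G2 and M phase 1.34, and Cst3 within P2 reversed to -0.15.

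At Leiden resolution 0.5 stem cells formed 5.05% at P2, with EYFP in 50%. Stem cell medians were 0.98 (astroglial), 1.68 (G2 and M phase), -0.53 (glycolysis) and 3.05 (subpallial), and the pallial median within P2 was 1.71. The stress median within P2 (-0.29) and the proneural median of cycling cells (-0.11) reversed. At resolution 2 excitatory neurons formed 61.9% at E18 and inhibitory neuroblasts 47.2% at P2.

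With both libraries clustered together stem cells formed 5.25% at E18 and 4.79% at P2, with EYFP in 52.7%. Stem cell medians were -1.39 (G2 and M phase) and -0.47 (glycolysis), and the pallial median within P2 was 1.75. The stress median within P2 (-0.33) and the G2 and M phase median of oligodendrocyte precursors (-0.037) reversed.

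With automatic doublet calls only, a setting added later, inhibitory neuroblasts formed 42.6% and stem cells 4.80% at P2, with EYFP in 65.0% of stem cells. Stem cell medians were 0.55 (proneural), 2.35 (G2 and M phase), -0.62 (glycolysis) and 3.03 (subpallial), and the pallial median within P2 was 1.64. Within P2 the medians of BMP and Id (-0.0041), cholesterol synthesis (-0.054), stress (-0.30), subpallial (0.084) and interferon genes (-0.0040) reversed.

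With the highest doublet scores removed before clustering, also added, stem cells formed 4.97% at P2, with EYFP in 50.9%. Stem cell medians were 0.99 (astroglial), 1.51 (G2 and M phase), -0.53 (glycolysis) and 3.07 (subpallial), and the pallial median within P2 was 1.71. The stress median within P2 (-0.29) and the proneural median of cycling cells (-0.059) reversed.

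With all cells clustered and the highest scores dropped afterwards, also added, inhibitory neuroblasts formed 47.8% and stem cells 4.92% at P2, with EYFP in 51.3% of stem cells. Stem cell medians were 0.98 (astroglial), 1.58 (G2 and M phase), -0.52 (glycolysis) and 3.07 (subpallial), and the pallial median within P2 was 1.71. The stress median within P2 reversed (-0.29).

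With 2.5% of the highest scores dropped, also added, inhibitory neuroblasts formed 43.6% at P2, and stem cell medians were 0.24 (proneural), 0.57 (astroglial) and 0.96 (G2 and M phase). With no cells set aside, also added, the G2 and M phase median was -1.27.

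The astroglial median of oligodendrocyte precursors reversed under TMM factors (-0.12) and without mitochondrial, ribosomal protein and haemoglobin UMIs (-0.031). As the mean of each cell's CPM, the pallial median within P2 was 1.32, and oxidative phosphorylation within P2 reversed (0.16). In cells with no UMI of 5 cycling markers, 18 at P2 and 69 at E18, the astroglial median was 0.72. The ependymal median of these stem cells reversed (-0.13). Over members with 50 or more UMIs the proneural median was 0.39 and that of glycolysis -1.24. EYFP stood in 16.9% of inhibitory neuroblasts after thinning, where fewer UMIs were read by construction, and in 18.2% at 2 or more UMIs.

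Pooled with maturing astrocytes, also added, stem cell medians were 0.98 (astroglial), 1.77 (G2 and M phase), -0.52 (glycolysis) and 3.19 (subpallial), and the pallial median within P2 was 1.65. Within P2 cholesterol synthesis (-0.042) and stress (-0.36) reversed. Depth sets the counting intervals of the stem cell ratios, with 549713 UMIs at E18 and 88449 in P2 cells without EYFP.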

Other observations

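The contrasts here were chosen after the data had been seen, and no explanation was tested for them.

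Cells with EYFP were set against cells without in the other P2 classes. The pallial list had a median log2 ratio of 2.07 in cycling cells (137 with, 168 without), 1.91 in oligodendrocyte precursors (46 and 35), 0.95 in inhibitory-lineage intermediate progenitors (76 and 82) and 0.91 in inhibitory neuroblasts or interneurons (313 and 850). It stood at 0.34 (-0.10 to 0.86) in maturing astrocytes (20 and 34) and 0.09 (-0.24 to 0.50) in excitatory neurons (177 and 39). The subpallial list stood, in the same order, at -0.27, 0.15, -0.28, -0.17, -1.18 and 0.32. Excitatory neurons without EYFP had a median of 4745 UMIs and those with it 13205, so EYFP can have been missed in the shallower cells.

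Cells with and without EYFP spread over the clusters of inhibitory neuroblasts in different proportions. Clusters 0 and 3 had EYFP in 106 of 288 and 114 of 241 cells, while clusters 7 and 9, among whose leading genes were Six3 and Nkx2-1, had it in 18 of 137 and 10 of 84 cells. Values for that class therefore also reflect its clusters.

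Dmrta2 stood at 2.62 in cycling cells (2.02 to 3.26), 2.54 in inhibitory-lineage intermediate progenitors, 2.07 in maturing astrocytes and 2.06 in inhibitory neuroblasts. It stood at -0.07 in excitatory neurons (-0.89 to 0.88). In oligodendrocyte precursors Dmrta2 had 17 UMIs against 0, 4.81-fold higher at the floor. Eomes stood at 4.18 in cycling cells (2.77 to 6.10) and 0.26 in excitatory neurons (-0.37 to 0.96), and had 22 UMIs against 0 in inhibitory-lineage intermediate progenitors. Six3 stood at -1.65 in cycling cells, -2.47 in inhibitory-lineage intermediate progenitors, -1.33 in maturing astrocytes and -1.09 in inhibitory neuroblasts. In oligodendrocyte precursors Six3 had 0 UMIs against 50, 19.6-fold lower at the floor. Nkx2-1, a gene of the medial ganglionic eminence, stood at -4.13 in cycling cells, -3.04 in oligodendrocyte precursors, -1.62 in inhibitory neuroblasts and 0.26 in inhibitory-lineage intermediate progenitors (8 and 11 UMIs). Gsx1 stood at 1.56 in inhibitory-lineage intermediate progenitors (1.01 to 2.15), -0.79 in oligodendrocyte precursors (-1.47 to -0.13), -0.44 in cycling cells and -0.42 in inhibitory neuroblasts, and Dlx1 at -1.18 in maturing astrocytes (-2.03 to -0.40), -0.28 in inhibitory-lineage intermediate progenitors (-0.43 to -0.12), -0.23 in cycling cells, 0.05 in excitatory neurons, 0.15 in oligodendrocyte precursors and 0.25 in inhibitory neuroblasts.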
